A study of Mus musculus with 12 samples.

How the data were processed

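Ribosome profiling and matched RNA sequencing were carried out in 32D cells, a mouse myeloid line that depends on interleukin-3 for growth. Wild-type (WT) cells were compared with KO1 and KO2, cells to which the labels give the genotype Nat10 deficiency. The labels do not say whether KO1 and KO2 are clones or were made with different guides. Each line gave 2 Input libraries (total RNA of the lysate) and 2 RPF libraries (ribosome-protected fragments), 12 libraries in 6 groups. Per the labels' protocols, cells were grown with 10% serum and 10 ng/ml interleukin-3 and were treated with 100 µg/ml cycloheximide for 10 min. Of each lysate, 100 µl were used for Input and 400 µl for RPF, and the RPF part was digested with RNase I for 45 min. Ribosomal RNA was depleted, and strand-specific libraries were read as paired ends of 150 bp.

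The deposited values are whole-number counts of reads per gene over coding exons, made by the authors with featureCounts 1.6.3 and Ensembl release 105 of GRCm39, per the file headers. The headers record strand option 1 and no option for reads that map to several places or to overlapping genes, and the names of the alignments carry a mark of duplicate removal. Such reads are therefore open to loss in genes with near-identical copies, in overlapping genes and in genes with many identical footprints. The submitters' processing notes also name cutadapt, Trimmomatic, Bowtie2, STAR and SAMtools, with no role given in the sources used here. Each table holds 22469 genes under Ensembl IDs, with coding exon coordinates and coding length.

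The deposited tables do not pair IDs with gene names. The table of gene names used here is of assembly GRCm38.p6, and 0 of the 22469 IDs matched it. No gene was named from its ID or position, so no ID was read as Nat10, the genotypes were not checked against its level, and whether a printed ID is that gene was not determined. For the same reason, of 25 gene lists fixed before the data were examined (1045 entries), the mitochondrially encoded proteins alone were tested, taken as the 13 genes of the mitochondrial chromosome. Groups that need no names were added after the data were seen: scran's mouse markers of G1, S and G2/M (each restricted to markers of 1 phase), chromosomes, and windows of 10 Mb with at least 20 tested genes.

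Depth ranged from 4424603 to 17311689 counts in the Input libraries and from 4370656 to 8303323 in the RPF libraries. Replicate pairs were compared with the sampling noise by a chi-square test over genes with at least 20 counts in the pair. The KO2 RPF pair gave 0.771 per degree of freedom, the KO2 Input pair 1.12, and the other pairs 1.45 to 2.64. The KO2 RPF pair was therefore counted as 1 sample, the rounded mean of both. The planned design had 6 RPF libraries; with this change the footprint fit had 5 libraries (2 residual degrees of freedom) and the joint fit 11 (5 residual degrees of freedom). KO2 footprints then have 1 sample, whose spread is taken from WT and KO1. The headers of both KO2 Input tables also name alignments of the same name, and of the pairs kept as 2 libraries this one lay closest to the sampling noise, though above it. Its 2 tables may therefore not be independent, and the SDs and p-values of KO2 RNA and efficiency rest on them. No source says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

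Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Input and RPF libraries were fitted separately with 1 mean per group. Translational efficiency, the ratio of footprints to RNA, was tested as an interaction in 1 model of both library types. Contrasts were the mean of KO1 and KO2 against WT, each line against WT, KO2 against KO1, and RPF against Input in WT. Standard errors are the log2 change divided by the root of the F statistic. Gene groups were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. Levels are TMM-scaled CPM (counts relative to library size) of all libraries together.

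The rule for named genes, fixed before the data were examined, ranked genes with an adjusted p under 0.05 and a mean CPM of at least 10 by their change in the mean of KO1 and KO2, among those that moved the same way in KO1 and KO2 (for RNA and footprints, with every library of both lines on the same side of WT). Its filters on symbols and biotypes could not be applied. Without names, 2 IDs that rose and 2 that fell are printed: the first of each direction for RNA, the first that fell in translational efficiency, and the first that rose in footprints. Which of the ranked IDs to print was decided after their values were seen, and the first that fell in footprints and the first that rose in translational efficiency were passed over, since they had almost no counts in KO1 and WT footprints respectively. ENSMUSG00000058427, printed for RNA, held 4 and 3 counts in the WT RPF libraries.

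The scripts were tested on simulated counts with 200 changed genes. For the mean of KO1 and KO2, a change of 1.5-fold was recovered for 88.1% of 67 genes in RNA (10639 genes tested), 74.6% in footprints (9914 genes) and 71.6% in translational efficiency (10448 genes); for 1.25-fold these shares were 71.6%, 44.8% and 34.3%. Calls among unchanged genes numbered 13, 6 and 5. A simulated rise of chromosome 8 by 1.25-fold in KO1 RNA was called with the preset correlation (camera adjusted p = 9.33e-297) and with an estimated one (camera adjusted p = 0.000139), with 0 of the other chromosomes called. In simulated KO1 footprints the same rise was called by both versions too. The simulated genes varied independently, so the version with an estimated correlation was far weaker even without correlation among genes. It still called the simulated rise, and the genes of other chromosomes were unchanged, unlike in the data. The simulation therefore does not explain a call that this version misses in the data, and such a call is left open.

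Because KO1 and KO2 share the WT libraries, their correlation was set beside 100 simulated draws of unchanged lines, on differences of log2 CPM with a prior count of 2. This measure replaced the fitted log2 changes after their correlations had been seen, so that observed and simulated values are measured alike; the fitted version is kept as an alternative. Alternatives fixed beforehand were DESeq2 1.42.0, its size factors, library size alone, no filter, a filter at a CPM of 5, nuclear genes, a replicate block, the compared groups alone, a joint fit, KO1 and KO2 libraries as 1 group, and each library left out. Alternatives chosen after seeing the data were both KO2 RPF tables as 2 libraries, both KO2 Input tables as 1, the correlation of fitted changes, and all genes but those of chromosomes 5, 8 and 19. Figures were drawn with matplotlib 3.10.9.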

Results

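The series asks how NAT10, the enzyme that writes N4-acetylcytidine into RNA, influences the translation of messenger RNA. Footprints and RNA were counted in WT, KO1 and KO2 32D cells, with 2 libraries per line and library type. Input libraries held 15930808 and 15220482 counts in WT, 17311689 and 16207659 in KO1, and 10634787 and 4424603 in KO2. RPF libraries held 6953215 and 6338292 counts in WT, 4370656 and 6485061 in KO1, and 6474604 and 8303323 in KO2. No ID was matched to Nat10, so the genotypes rest on the labels, and no printed ID was checked for being the targeted gene. The KO2 RPF pair differed by less than the sampling noise and was counted as 1 sample. The coefficient of variation within groups beyond sampling noise, as estimated by edgeR, was 0.0274 in RNA and 0.0301 in footprints. It may be technical, since replicates are not known to be separate cultures.

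RNA was first compared between Nat10-deficient and WT cells. Of 10859 genes, 3137 were higher and 3289 lower in the mean of KO1 and KO2, and most of these changes were small, with a median size of 0.34 on the log2 scale. Library size alone gave 2707 higher and 3759 lower, and DESeq2 gave 2536 and 2406, where higher genes were the larger side. At least 2-fold changes were called for 194 higher and 297 lower genes. Among genes with a mean CPM of at least 10 that moved the same way in both lines, the one that fell most was ENSMUSG00000023272 on chromosome 15 (88703915 to 88710636, GRCm39), whose RNA was 357 ± 15.1 CPM (SD, n = 2) in WT, 31.1 ± 1.82 in KO1 and 34.2 ± 3.36 in KO2. Its log2 change was -3.44 (SE 0.04, adjusted p = 5.10e-33), and KO1 and KO2 did not differ past the threshold (adjusted p = 0.103). By the same rule the gene that rose most was ENSMUSG00000058427 on chromosome 5 (91051804 to 91053060), at 1.81 ± 0.282 CPM in WT, 126 ± 5.06 in KO1 and 3.96 ± 0.611 in KO2. Its log2 change was 6.11 in KO1 (SE 0.10, adjusted p = 7.10e-30) and 1.18 in KO2 (SE 0.25, adjusted p = 0.000202), and the lines differed (adjusted p = 3.80e-26). With the KO1 and KO2 libraries as 1 group, so that the difference between the lines entered the spread, the calls fell to 678 higher and 663 lower, and ENSMUSG00000058427 was no longer called, although its log2 change was 5.20, against 3.64 with separate lines (edgeR adjusted p = 0.118, against 2.54e-75 to 8.06e-13 under its other settings).

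KO1 and KO2 had some RNA calls in common and differed in many others. In KO1 3416 genes were higher and 3301 lower than in WT, and in KO2 2990 were higher and 3041 lower. Of these, 1639 were higher in both lines and 1625 lower in both, and 940 moved in opposite directions. Independent lists of these sizes would share 941 higher and 924 lower genes, with 1866 in opposite directions. Refits of simulated unchanged lines made at most 1 call per line, so they set no level for these overlaps, and the independent lists leave out the shared WT libraries. At least 2-fold changes in both lines were called for 70 higher and 119 lower genes. Directly compared, KO2 was higher than KO1 at 2960 genes and lower at 3307. Scaled by library size alone, KO1 RNA gave 2825 higher and 3974 lower genes, and the comparison of KO2 with KO1 gave 3413 and 2835, so that the larger side turned in both. Across genes, which are not independent replicates, the KO1 and KO2 changes correlated at Pearson r = 0.330 and Spearman rho = 0.420, against 0.386 and 0.371 in simulated unchanged lines. Their covariance was 0.113, against 0.0103 simulated. The simulated lines share the WT libraries at the fitted spread, so the excess of the covariance is beyond what that sharing gives, while Pearson r showed no excess. A deviation common to both WT libraries beyond that spread would also be shared. It could not be tested, since the WT libraries could not be split with 2 in each part, so part of the excess may still come from the shared controls.

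**Figure D1:**
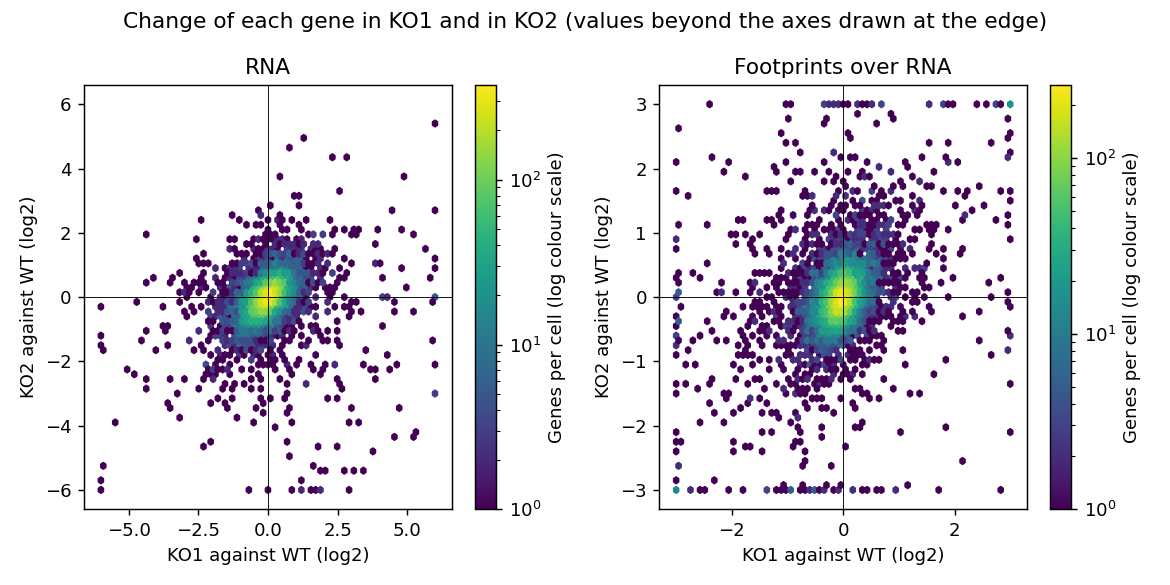
Each panel sets the log2 change of every tested gene in KO1 (x axis) against its change in KO2 (y axis), for RNA on the left and for footprints over RNA on the right, with colour for the number of genes per cell on a log scale. Values beyond the axes are drawn at the edge; in RNA 3264 genes were called in the same direction in both lines and 940 in opposite directions.

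The RNA changes of KO1 followed chromosome position. On chromosome 8, 351 genes were higher and 73 lower of 609 tested, with a median log2 change of 0.33, and on chromosome 19, 54 were higher and 237 lower of 402, with a median of -0.33. The rise on chromosome 8 lay from 30 Mb to the end of the chromosome (330 higher and 41 lower of 511 genes, median 0.38), and its first 30 Mb had a median of -0.05. On chromosome 19 the genes outside 10 to 30 Mb had a median of -0.36 (32 higher, 212 lower of 329), against -0.04 between 10 and 30 Mb. On chromosome 5, genes between 20 and 60 Mb had a median of -0.39 (12 higher, 116 lower of 158), against 0.00 for the rest of that chromosome. Per library, the median over chromosome 8 from 30 Mb was 0.38 ± 0.00143 (SD, n = 2) in KO1 and -0.05 ± 0.00791 in KO2. Over the 20 chromosomes tested, camera called chromosomes 8 (adjusted p = 9.58e-09) and 19 (adjusted p = 9.09e-09) in KO1 RNA. Both calls held with an estimated correlation (adjusted p = 0.0468 and 0.0299). No chromosome was called in KO2 RNA (0 of 20 also at an unadjusted camera p under 0.05), and the difference between the lines was called for chromosomes 5, 8 and 19 (adjusted p = 0.00710, 4.95e-12 and 1.34e-15), though not with an estimated correlation (adjusted p = 0.334 for each). For the difference between the lines the estimates were 0.059 on chromosome 8 and 0.058 on chromosome 19, above the preset 0.01. A larger correlation among genes may therefore have lost these 2 calls, and their preset p-values may be too small. On chromosome 5 the estimate was 0.0083, below the preset. The bounds within chromosomes were chosen after the data were seen.

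**Figure D2:**
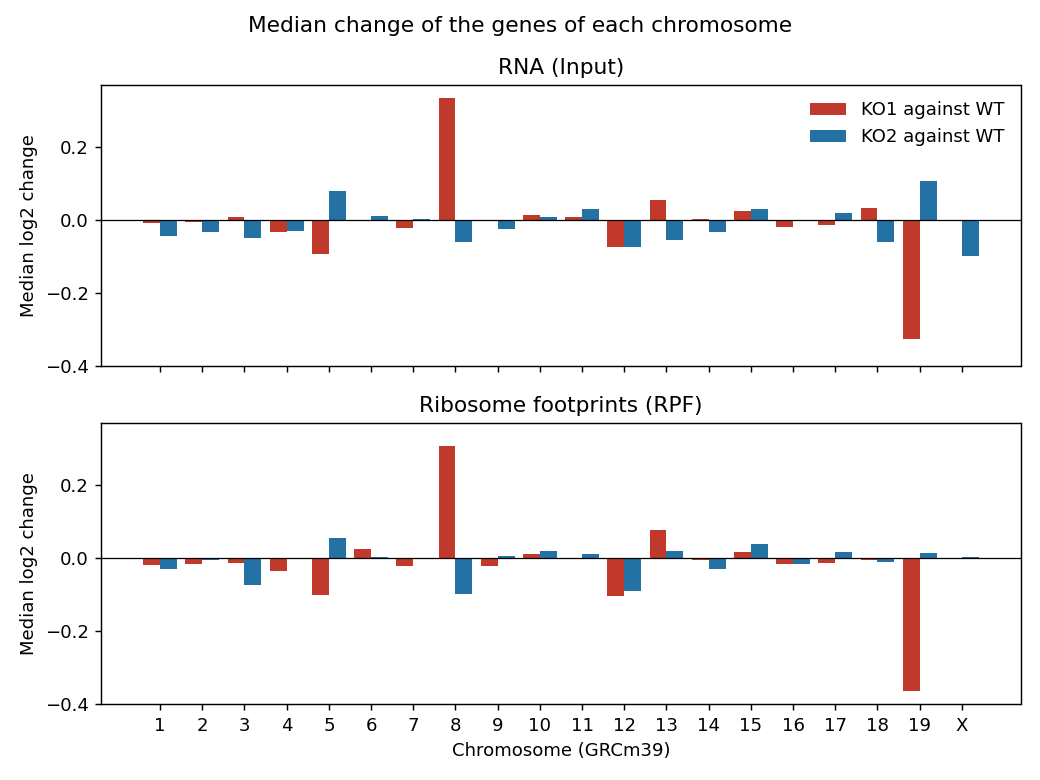
Bars give the median log2 change against WT of the tested genes of each chromosome (x axis, GRCm39) in KO1 and KO2, for RNA above and footprints below. In KO1, chromosome 8 stands at 0.33 in RNA and 0.31 in footprints, and chromosome 19 at -0.33 and -0.37.

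One window of 10 Mb was called in both lines: chromosome 13 from 20 to 30 Mb. In KO1 RNA 48 of its 72 genes were higher and 6 lower (median 0.35, camera adjusted p = 2.70e-08 over 189 windows), and in KO2 RNA 37 were higher and 9 lower (median 0.20, adjusted p = 4.07e-05). Neither call held with an estimated correlation (adjusted p = 0.288 and 0.869). Of the 72 genes, 50 had a single coding exon, and these had medians of 0.52 in KO1 and 0.27 in KO2. The other 22 genes of the window had medians of 0.05 and 0.00, and genes with a single coding exon elsewhere had medians of 0.00 and 0.12.

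**Figure D3:**
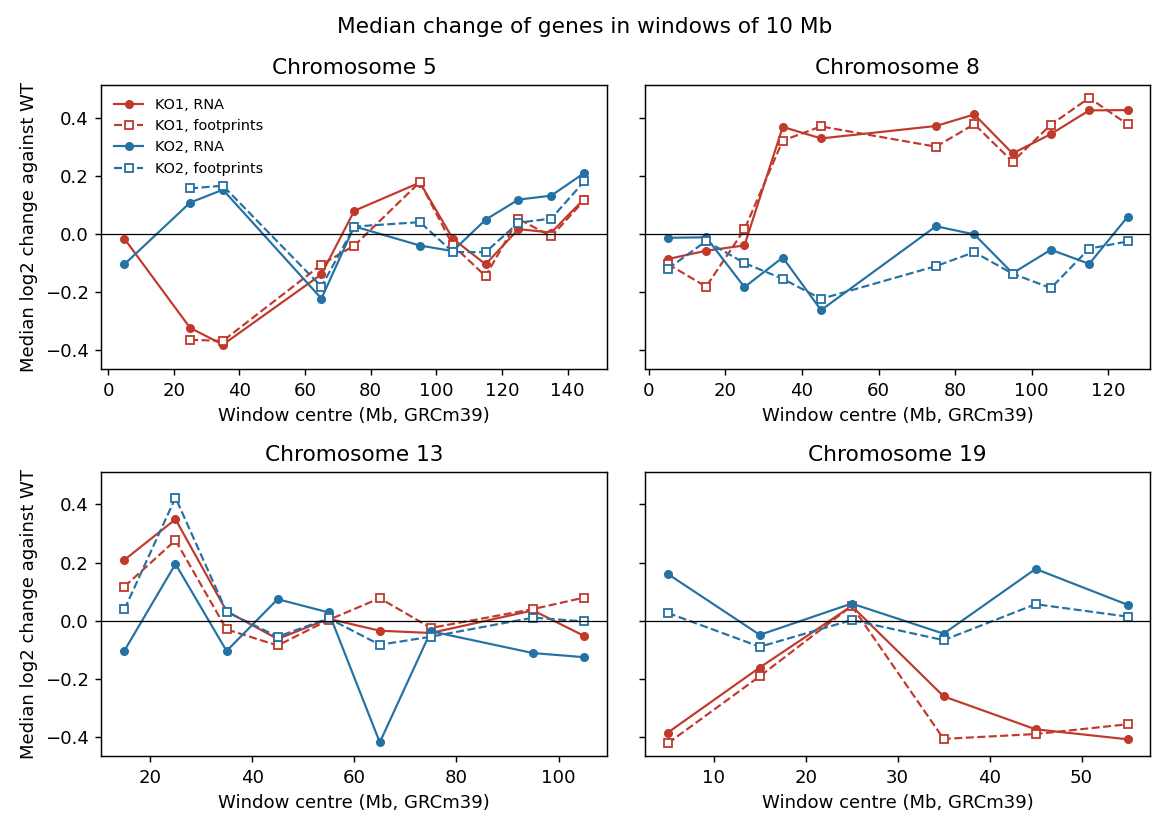
Points give the median log2 change against WT of the genes in each window of 10 Mb with at least 20 tested genes (x axis, window centre in Mb, GRCm39), for RNA (filled circles) and footprints (open squares) of KO1 and KO2. On chromosome 8 the KO1 medians rise from 30 Mb on, and on chromosome 13 both lines are above 0 between 20 and 30 Mb.

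G2/M markers alone among the cell cycle sets were called in KO1 RNA. Of 50 tested, 8 were higher and 32 lower (median -0.23, camera adjusted p = 0.0316 over 4 sets; adjusted p = 0.191 with an estimated correlation), against 10 higher and 17 lower in KO2 (median -0.15, adjusted p = 0.823). The difference between the lines was not called for these markers in RNA (adjusted p = 0.202). Of 90 S markers, 25 were higher and 42 lower in KO1 RNA (adjusted p = 0.202), and in KO2 31 were higher and 25 lower (adjusted p = 0.979). Of 49 G1 markers, 20 were higher and 13 lower in KO1 (adjusted p = 0.471), and in KO2 17 were higher and 19 lower (adjusted p = 0.979). The mitochondrially encoded proteins took 0.00410 to 0.0120% of the counts of a library. Of the 13 genes, 5 had 0 counts in all 12 libraries, and 6, these included, had fewer than 2 in total. The list was thus measured only in part, and its share differed between the WT Input replicates (0.00976 and 0.00566%). Of the 7 genes that could be tested in RNA, 3 were higher and 0 lower in the mean of KO1 and KO2 (6 higher and 0 lower adjusted over the list alone). Their median of 0.57 was not called (adjusted p = 0.314, and 0.580 with an estimated correlation).

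Footprints mostly followed RNA. Of 10100 genes, 2301 were higher and 2274 lower in the mean of KO1 and KO2, with 161 and 238 at least 2-fold changed. Across 10071 genes tested in both library types, footprint and RNA changes correlated at Pearson r = 0.816 and Spearman rho = 0.777, across genes and not across independent replicates. Of 6205 genes called in RNA, 90.2% moved the same way in footprints, and of 3807 called in both, 79 moved in opposite directions. ENSMUSG00000023272 fell in footprints from 477 ± 30.6 CPM (SD, n = 2) in WT to 38.3 ± 2.72 in KO1 and 44.7 in KO2, a log2 change of -3.50 (SE 0.06, adjusted p = 2.00e-80). DESeq2 called fewer footprint changes, 1335 higher and 1042 lower. With the KO1 and KO2 libraries as 1 group, 606 were higher and 542 lower.

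Footprints were also compared line by line. In KO1 2639 genes were higher and 2501 lower, and in KO2 1867 were higher and 1673 lower. KO2 footprints entered as 1 sample, assumed to vary like WT and KO1, in every KO2 call and every call between the lines, for footprints and for translational efficiency. In both lines 1215 were higher and 1058 lower, and 317 moved in opposite directions. Independent lists would share 488 and 414, with 899 in opposite directions, and simulated unchanged lines again made at most 1 call per line. KO2 was higher than KO1 at 1562 genes and lower at 1818. The KO1 and KO2 changes correlated across genes at r = 0.428 and rho = 0.519, against 0.394 and 0.358 simulated, with a covariance of 0.127 against 0.0144. In KO1 the footprint medians were 0.31 on chromosome 8 (adjusted p = 2.72e-08) and -0.37 on chromosome 19 (adjusted p = 4.87e-10). With an estimated correlation neither passed (adjusted p = 0.258 and 0.0992). The estimates, 0.0094 and -0.0017, lay below the preset 0.01, so a larger correlation among genes is not what lost these calls. The window on chromosome 13 had footprint medians of 0.28 in KO1 and 0.42 in KO2 (adjusted p = 2.05e-06 and 8.08e-13; adjusted p = 0.868 and 0.998 with an estimated correlation). G2/M markers (5 higher, 28 lower of 49, adjusted p = 0.00667) and S markers (14 higher, 37 lower of 89, adjusted p = 0.0297) were lower in KO1 footprints; both had an adjusted p of 0.159 with an estimated correlation. The difference between KO2 and KO1 was called for G2/M markers in footprints (18 higher, 5 lower, adjusted p = 0.0446; 0.228 with an estimated correlation). G1 markers were not called in either line (17 higher, 9 lower in KO1, adjusted p = 0.407; 12 higher, 7 lower in KO2, adjusted p = 0.713). Of 6 mitochondrially encoded proteins tested, 3 were higher and 0 lower in the mean (3 and 0 adjusted over the list alone; set adjusted p = 0.191, and 0.497 with an estimated correlation). Scaled by library size alone, KO1 footprints gave 2142 higher and 3079 lower genes, and the comparison of KO2 with KO1 gave 1879 and 1461. By DESeq2 the 3 comparisons gave 2978 calls in KO1, 1497 in KO2 and 1473 between the lines.

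Fewer genes were called in translational efficiency than in RNA, by a test that recovered fewer of the small simulated changes (34.3% against 71.6% at the smallest size). Of 10677 genes, 309 were higher and 470 lower in the mean of KO1 and KO2, of which 12 and 7 changed at least 2-fold. Among genes with a mean CPM of at least 10, the one that fell most was ENSMUSG00000015647 on chromosome 2 (179818343 to 179867595), with a coding length of 11154 bp. Its footprints were 750.3 ± 12.5 CPM (SD, n = 2) in WT, 178 ± 4.78 in KO1 and 158 in KO2, while its RNA was 845 ± 21.3, 449.8 ± 3.03 and 461 ± 1.05 CPM. Its footprints over RNA changed by -1.17 on the log2 scale in KO1 (SE 0.05, adjusted p = 1.73e-23) and by -1.37 in KO2 (SE 0.06, adjusted p = 1.43e-23), and the lines differed by -0.21 (adjusted p = 0.0357). The efficiency of ENSMUSG00000027185 on chromosome 2 (103552171 to 103588123) rose, although it was not determined whether this ID is the gene targeted in both lines, nor whether its fragments come from a construct. Its values are open to being those of the targeted locus itself, since the table of gene names places Nat10 on chromosome 2 as well. That chromosome holds 8.24% of the rows, ENSMUSG00000015647 among them, so this match identifies no gene. Its footprints were 114 ± 11.9 CPM (SD, n = 2) in WT, 2631 ± 952 in KO1 and 10008 in KO2, while its RNA was 89.5 ± 4.06, 110.2 ± 2.78 and 309 ± 4.47 CPM. Its footprints over RNA changed by 4.22 in KO1 (SE 0.16, adjusted p = 2.20e-26) and 4.66 in KO2 (SE 0.16, adjusted p = 9.52e-28), and the fitted difference of KO2 from KO1 (log2 0.44, adjusted p = 0.0398) was smaller than the gap between its KO1 footprint replicates, so the lines are not set apart by it. It ranked first among the footprint rises and second in efficiency, behind a gene with 0 WT footprint counts, for which no fold is given. Its KO1 replicates differed by 0.77 on the log2 scale, more than those of any of 184 genes of like CPM.

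**Figure D4:**
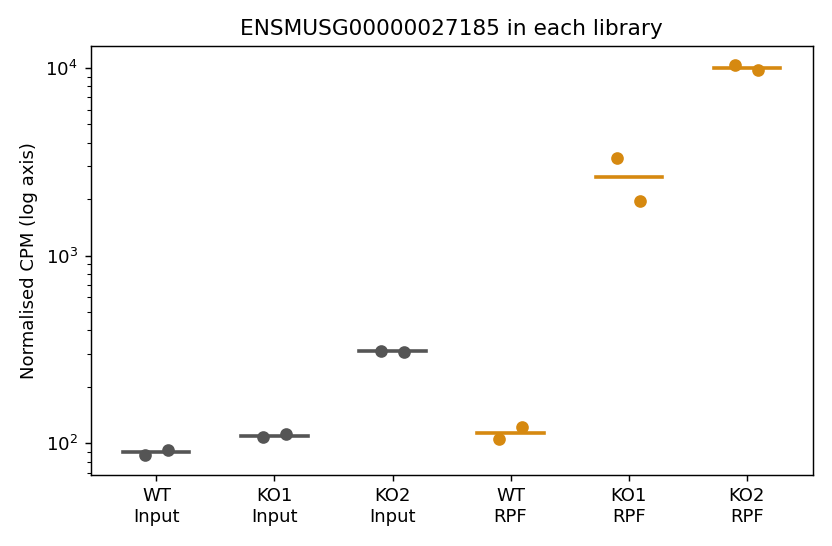
Points give the TMM-scaled CPM of ENSMUSG00000027185 (y axis, log scale) in each library, grouped by line and library type, and lines give group means. WT footprints averaged 114 CPM and KO2 footprints 10008 CPM, where the KO2 RPF points are the pair counted as 1 sample.

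Some efficiency calls were common to both lines. In KO1 217 genes were higher and 341 lower, and in KO2 498 were higher and 630 lower. In both lines 102 were higher and 94 lower, and 15 moved in opposite directions, against 10.1, 20.1 and 28.7 for independent lists, which leave out the shared WT libraries. Simulated unchanged lines made at most 1 call per line and set no level for this overlap. KO2 was higher than KO1 at 579 genes and lower at 464. Across genes the changes correlated at r = 0.378 and rho = 0.331, against 0.389 and 0.360 simulated, with a covariance of 0.0573 against 0.0305. Camera called 0 chromosomes in translational efficiency in KO1 (0 at an unadjusted p under 0.05) and 0 in KO2 (2 unadjusted), and chromosome 8 from 30 Mb had medians of -0.04 in KO1 and -0.07 in KO2. None of the cell cycle sets was called either; in the mean of KO1 and KO2, 5 G1 markers were higher and 4 lower (adjusted p = 0.786), 2 S markers higher and 5 lower (adjusted p = 0.911), and 1 G2/M marker higher and 2 lower (adjusted p = 0.911). Of the 7 mitochondrially encoded proteins tested, edgeR called 0, also adjusted over the list alone and at an unadjusted p under 0.05, and DESeq2 called 0 (set adjusted p = 0.911, and 0.961 with an estimated correlation).

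The counts and the direction of the efficiency calls depended on the test. DESeq2 gave 198 higher and 165 lower genes for the mean, 136 and 97 in KO1, 300 and 279 in KO2, and 533 calls between the lines. With the KO1 and KO2 libraries as 1 group 4 genes were higher and 1 lower. The lower one was ENSMUSG00000015647 (adjusted p = 0.00195), and ENSMUSG00000027185 was not called, although its log2 change was 4.26, against 4.44 with separate lines (edgeR adjusted p = 0.565, against at most 1.79e-19 under its other settings). With DESeq2's size factors in edgeR the KO1 split was 266 higher and 263 lower, and with library size alone 268 and 272. With only the compared groups in the fit the KO2 split was 750 higher and 424 lower. Counting both KO2 RPF tables as 2 libraries raised the KO2 calls to 1866 and those between lines to 1779, and counting both KO2 Input tables as 1 lowered them to 709 and 640. Without WT RPF replicate 1 or 2 the mean gave 440.0 or 518 calls and KO1 gave 296 or 356, and without KO2 Input replicate 1 KO2 gave 658 and the comparison of lines 576.

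Within WT cells, footprints relative to RNA varied with coding length. Of 10677 genes, 4189 had more and 4207 fewer footprints than their RNA share, with 948 and 2120 at least 2-fold apart. These counts are open to the loss of reads in near-identical copies, in overlapping genes and by duplicate removal, which was not tested. Across 8655 genes with a mean CPM of at least 10, the WT log2 ratio of footprints to RNA fell with coding length (Spearman rho = -0.319, across genes, which are not independent replicates). Among genes of up to 1000 bp the median showed no steady fall, at 0.40 for the 131 genes of up to 300 bp, 0.38 for the 860 genes of 300 to 600 bp and 0.44 for the 1536 genes of 600 to 1000 bp. It was 0.02 for the 2275 genes of 1500 to 2500 bp and -0.74 for the 404 genes over 5000 bp. The efficiency change in Nat10-deficient cells showed little of this trend (rho = -0.0769 for the mean, -0.100 in KO1 and -0.0336 in KO2). In KO1 its median fell steadily, from 0.03 for genes of up to 300 bp to -0.07 for those over 5000 bp. In KO2 it showed no steady fall.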

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

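The tests of matched sets on chromosomes 5, 8 and 19 were stated before their results were seen, on segments bounded after the KO1 medians were seen; the other tests in this part, and the comparison of KO2 with KO1 within chosen regions, were chosen after the results were seen. Tested as whole chromosomes, KO2 and KO1 differed by a direct test on 3. In RNA the median log2 difference of KO2 from KO1 was 0.14 on chromosome 5, -0.36 on chromosome 8 and 0.44 on chromosome 19, and in footprints it was 0.11, -0.41 and 0.38. None of these 6 calls held with an estimated correlation. By windows of 10 Mb the lines also differed on chromosome 3 from 30 to 40 Mb, which was called in neither line against WT. In RNA 2 of its 31 genes were higher and 22 lower in KO2 (median -0.47, camera adjusted p = 0.000179 over 189 windows). With an estimated correlation this call was lost (adjusted p = 0.845). Its footprint median was -0.52. Smaller RNA differences were called in windows of chromosomes 10 and 17 (medians -0.09 and 0.11).

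In KO1 RNA the medians of chromosome 8 from 30 Mb, chromosome 19 outside 10 to 30 Mb and chromosome 5 from 20 to 60 Mb were 0.38, -0.36 and -0.39, and random sets matched on expression and coding length (a permutation test over genes) stayed within -0.15 and 0.14 and gave medians as far out with p = 0.0001 for each, the smallest that 10000 draws can give and one that ignores how the segments were chosen, which argues against both properties as the cause but is no further evidence of the shifts. The KO2 medians of the same genes were -0.056, 0.14 and 0.13, against -0.085 to 0.069, -0.11 to 0.11 and -0.14 to 0.14 in KO2 for the matched sets. Each had the opposite sign to the KO1 shift and fell short of it by more than those ranges. This argues against a loss of Nat10 that shifts both lines alike as the whole cause. The KO2 median on chromosome 19 (0.138) also lay above its whole range (highest 0.110), so KO2 RNA was itself slightly raised there, with 0.03 in footprints. A hypothesis is that KO1 cells may carry a different dosage of these segments. The footprints of the chromosome 8 segment shifted with its RNA (median 0.36), as dosage would require, but so would any change in RNA level, and dosage and regulation cannot be told apart without a measurement of DNA. An effect of Nat10 loss that differs between the lines stays open, since the extent of the loss was not measured here.

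ENSMUSG00000027185 differed between KO2 and KO1 by 1.47 in RNA and 1.90 in footprints on the log2 scale, and by 0.44 in footprints over RNA, which is within the gap between its KO1 footprint replicates and does not set the lines apart. Its RNA level does not account for its footprints, since the smaller of its changes of footprints over RNA was 4.22, and neither does 1 aberrant library, since the lowest KO1 or KO2 library held 16.3 times the CPM of the highest WT library. Fragments that do not come from ribosomes remain a candidate source: the KO1 replicates of this gene differed by 0.77 on the log2 scale, more than in 100% of 184 genes within 4-fold of its CPM, whose largest difference was 0.27. The ID lies on chromosome 2, where the table of gene names places Nat10, but 8.24% of the rows lie there too. It was not determined whether this ID is the targeted gene. In that case fragments of a construct could add to its footprints, so neither such fragments nor a change in its translation is excluded.

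ENSMUSG00000058427 differed between KO2 and KO1 by -4.94 in RNA and -5.19 in footprints. ENSMUSG00000015647 differed by -0.20 in footprints and -0.21 in footprints over RNA. The G2/M markers differed in footprints by a median of 0.24 (camera adjusted p = 0.0446, and adjusted p = 0.228 with an estimated correlation). In the window of chromosome 13 from 20 to 30 Mb, footprints over RNA differed by a median of 0.11 (21 genes higher and 3 lower in KO2 of 70, camera adjusted p = 6.13e-07 over 188 windows, and adjusted p = 0.248 with an estimated correlation).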

How the results depend on the processing

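The alternatives that use the KO2 tables differently, correlate fitted changes, or leave out chromosomes 5, 8 and 19, were chosen after seeing the data. Counts of calls stayed within 1.5 times the main count except as follows, and the cause was not tested except where construction gives it. With the KO1 and KO2 libraries as 1 group, in which the difference between the lines counts as spread, calls for the mean numbered 1341 in RNA, 1148 in footprints and 5 in translational efficiency. DESeq2 gave 2377, 2978, 1497 and 1473 footprint calls (mean, KO1, KO2 and KO2 against KO1) and 363, 233, 579 and 533 in translational efficiency. Both KO2 RPF tables as 2 libraries gave 1866 and 1779 efficiency calls for KO2 and KO2 against KO1, and both KO2 Input tables as 1 gave 709 and 640.

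Leaving out 1 library at a time gave 440.0 to 859 efficiency calls for the mean, 296 to 560.0 for KO1, 658 to 1254 for KO2 and 576 to 1132 between the lines. A group left with 1 library is assumed to vary like the others. Among genes with a mean CPM of at least 10 the correlation of KO1 and KO2 changes was 0.399 in RNA and 0.496 in footprints. With fitted log2 changes it was 0.245 in RNA, 0.311 in footprints and 0.410 in translational efficiency, and at that CPM 0.388, 0.448 and 0.392.

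No pairing of libraries by replicate number was seen: correlations of replicate differences between groups lay between -0.0356 and 0.0363. Sampling noise in these differences can hide a shared deviation, so pairing is not excluded. The replicate block gave 6483 RNA calls for the mean. ENSMUSG00000023272 kept its fall in RNA under all 17 alternatives (-3.51 to -3.40), and ENSMUSG00000015647 its fall in efficiency under all 23 (-1.30 to -1.24). ENSMUSG00000027185 was called in footprints under all 17 (5.29 to 5.68) and in efficiency under 22 of 23. The KO1 RNA median of chromosome 8 ranged from 0.27 to 0.34 and that of chromosome 19 from -0.39 to -0.30. Scaling moved the median of all genes by at most 0.0837. In simulated counts at these depths, changes of the smallest simulated size in the mean of KO1 and KO2 were recovered for 34.3% of genes in translational efficiency, 44.8% in footprints and 71.6% in RNA.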

Other observations

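The test with the trend on coding length removed was stated before its result was seen; the test of sets matched on expression was chosen after. Genes with higher translational efficiency in the mean of KO1 and KO2 had short coding regions. Their median coding length was 1176 bp over 309 genes, and random sets matched on expression (a permutation test over genes) were as short with p = 0.0001, the smallest that 10000 draws can give, so the expression level of the genes does not account for it. With the trend on coding length removed from every library, 404 genes were higher and 333 lower. The higher ones had a median of 1284 bp, and a permutation test over matched genes again gave p = 0.0001. All 309 genes stayed among the 404, so this p-value rests largely on the same genes and is no separate evidence. More genes were higher and fewer lower than before, so the general level may have moved with the trend. The calls of the 309 genes outlasted this removal, but it cannot decide whether a coding length trend of all genes contributes. Neither test was made for KO1 or KO2 alone. Duplicate removal, which limits the footprints a short gene can keep, and loss of reads in genes with near-identical copies may contribute. So may a biological preference for short coding regions, and none of these was tested. With KO1 and KO2 libraries as 1 group, only 5 efficiency changes were called, and coding length was not tested among them.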
